A study of Ruditapes philippinarum with 15 samples.

How the data were processed

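Total RNA of hepatopancreas was extracted with a column kit for tissue (Qiagen RNeasy) and amplified and labelled with Cyanine 3 for 1-colour Agilent arrays, per the labels' protocols. The 15 scanner files were written with Agilent Feature Extraction 9.5.1.1 under protocol GE1-v5_95_Feb07, per the file headers. They hold linear intensities of each spot: the raw mean signal, the median of the local background, and a processed signal that the software had background-subtracted and detrended within the array but not normalized between arrays, per the file headers. Per the file headers, the software also set flags of 0 or 1 that the authors deposited with each spot, among them whether it is well above background, saturated or an outlier.

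The series value table deposited by the authors holds linear intensities as well. Its log2 values followed the processed signals of the same array with a correlation over 0.999 on each of the 15 arrays, so its rows were matched by spot number, and its values are blank at control spots and where the software did not find the spot. Its scale is linear and it is not centred. The column medians for replicates 1 to 5 were 195, 199.7, 204, 184 and 212 at Chioggia, 249, 205, 177, 212 and 185 at Colmata, and 206, 189.5, 208, 231 and 207 at Marghera. The method by which that table was normalized between arrays is not given in the sources used here and stays unknown. The table was used only as an alternative.

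For the analysis, log2 of the processed signal was taken and the 75th percentile of each array was subtracted, which sets the arrays on a common scale and removes any change of the whole transcriptome that moves all probes together. Of 14156 probes with 1 spot each, 45 spots flagged as outliers were left out as missing values, and control spots were not used. The 1 saturated spot was kept. A probe was tested if it was well above background on at least 4 of the 5 arrays of at least 1 site, which left 9194 probes (64.9%). The filter keeps probes that are silent at some sites, and for these the text gives only a bound in the main values. It sets the mean of all 5 arrays of the brighter site against a floor on each array of the dimmer site. That floor was the lowest signal of probes well above background, or the probe's own signal where that was higher. Where arrays of the brighter site were themselves not well above background, the bound is not firm. Fitted log2 differences of these probes are given only under normexp. One linear model with the site as its only term was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom). The comparisons were Marghera minus Chioggia, Marghera minus Colmata, Colmata minus Chioggia and Marghera minus the mean of the others. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Log2 differences are the first-named site minus the second.

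The sites, the tests, the filter, the alternatives, 21 gene lists, 7 lists for other tissues and food, and the rule for named items were chosen before the data were examined. The probe descriptions hold no gene name, and 0 probe names or contigs matched the table of 48037 genes used here, so the lists matched 0 probes. The list tests, planned with limma's camera, were therefore not run. Because the probes have no gene names, at most 2 IDs that rose and 2 that fell were named per comparison, in place of the longer lists first planned. They are those with the largest change among probes past the threshold whose arrays did not overlap between the sites compared, with 1 probe per contig. For the probes shared by both Marghera comparisons they are those with the largest smaller change, and there the arrays may overlap. No genome positions or annotation were used here.

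Precision on arrays is set by the number of arrays and by signal over background. Among tested probes, 127 pairs have the same sequence, and their spots gave an SD of 0.111 log2 for 1 spot, where the median residual SD between arrays of a site was 0.347. Correlations of the Marghera minus Chioggia changes between such pairs were 0.98 over pairs. No array was a copy of another: the closest pairs within the sites differed with an SD of 0.68, 0.75 and 0.75 log2 over probes, where the spots of one sequence differ by 0.157. The fit was tested on simulated data with the real spreads and 200 changed probes among 9194. For Marghera against Chioggia it called 11.9% of changes of 0.5 log2, 64.2% of changes of 1 log2 and 87.9% of changes of 2 log2, and 4.39% of its calls were false.

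The arrays lay on 2 slides, each with its own scan. Chioggia had 3 arrays on slide 1 and 2 on slide 2, Colmata and Marghera 2 and 3. A slide term passed the threshold for 30 probes by limma, and 1087 had an unadjusted p under 0.05, where chance gives 459.7. Alternatives were normexp background correction (offset 50) of the raw signals, quantile, cyclic loess and median scaling, no filter and a filter on all arrays, the series value table, slide or replicate number as a block, fits of only the sites compared, array weights, a variance trend with robust estimation, a 2-fold minimum, and leaving out each array. Chosen after seeing the data were fits within each slide, the row on the slide as a block, a fit without Colmata replicate 3 and Marghera replicate 1 together, and normexp with outlying backgrounds replaced. Both normexp settings add the offset of 50 to each corrected signal, which shrinks the log2 differences of dim probes. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.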

Results

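Gene expression was measured in the hepatopancreas, the digestive gland, of Manila clams (Ruditapes philippinarum) collected in January at 3 places in the Venice lagoon. Chioggia and Colmata are described by the submitters as having low pollution and Marghera as polluted, and the study set the polluted place against the other two. Each site was represented by 5 arrays, 15 in all, each read in 1 colour and carrying 14156 probes of 60 bases. Between 8797 (Colmata replicate 1) and 9760 (Marghera replicate 1) probes per array were well above background. The mean number was 9328 ± 149.7 (SD, n = 5) at Chioggia, 9338 ± 342 (SD, n = 5) at Colmata and 9164 ± 370 (SD, n = 5) at Marghera. Both slides held arrays of all 3 sites. The probes are named by assembled transcript fragments (contigs), with no gene name in the files used here, so probes are reported by ID and sequence. The labels do not say whether the 5 arrays of a site came from separate clams or pools, so the p-values measure only the spread between these samples, and the number of arrays limits their precision.

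The Marghera arrays lay apart from both other sites on the principal component that carried the most variance. This component held 14.6% of the variance over the tested probes, and the Marghera arrays had scores from 23.3 to 44.1, while the Chioggia and Colmata arrays lay between -21.4 and -3.08. The next component, with 12.1% of the variance, did not follow the sites. Colmata replicate 3 (46.7) and Marghera replicate 1 (38.2) were at one end of it, and the other 13 arrays lay between -26.7 and 18.2.

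**Figure D1:**
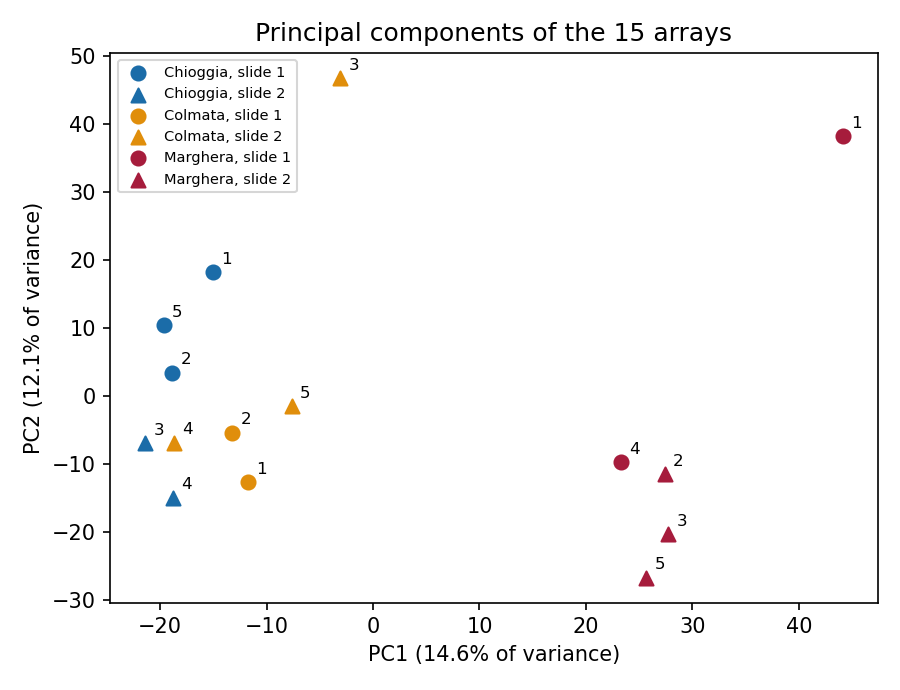
Scores of the 15 arrays on the first principal components of the normalized log2 signals, in arbitrary units, with colour for the site, symbol for the slide and the replicate number beside each point. The 5 Marghera arrays lie between 23.3 and 44.1 on PC1, above all arrays of the other sites. On PC2 the Chioggia arrays of slide 1 (3.39 to 18.2) lie above those of slide 2 (-15.0 and -6.93). The same holds at Marghera (-9.78 and 38.2 on slide 1, -26.7 to -11.5 on slide 2). At Colmata the slides overlap (-12.7 and -5.42 on slide 1, -6.90 to 46.7 on slide 2).

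The first comparison asked how clams from polluted Marghera differed from clams of Chioggia. Expression differed by more than the spread between arrays for 463 of the 9194 probes tested, 263 higher and 200 lower at Marghera, from 440 contigs. The median size of these changes was 1.05 on the log2 scale, and 246 probes changed by at least 2-fold, of which 151 were higher and 95 lower. The probes named as higher at Marghera were ruditapesP_c10932_1 and ruditapes_c21049_S. Of the probes named as lower, ruditapes2_lrc4903_AS was not well above background on any Marghera array, and ruditapesP2_lrc5035_1 was so on 2 of the 5.

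The signal of ruditapesP_c10932_1 (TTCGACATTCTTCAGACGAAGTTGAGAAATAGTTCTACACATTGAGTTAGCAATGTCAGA) was 169 ± 66.8 (SD, n = 5) at Marghera and 12.6 ± 7.97 (SD, n = 5) at Chioggia, where 3 of the 5 arrays were well above background. Its normalized level was 3.99 log2 higher at Marghera (SE 0.46; limma with Benjamini-Hochberg adjustment, adjusted p = 1.5e-04). The signal of ruditapes_c21049_S (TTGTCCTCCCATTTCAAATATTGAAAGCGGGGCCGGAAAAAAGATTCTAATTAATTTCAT) was 145 ± 53.1 (SD, n = 5) at Marghera against 13.98 ± 6.43 (SD, n = 5) at Chioggia, a rise of 3.40 log2 (SE 0.42; limma, adjusted p = 2.7e-04). On Chioggia replicate 1 this probe was not well above background, and without that array the rise was 3.02 log2. For ruditapes2_lrc4903_AS (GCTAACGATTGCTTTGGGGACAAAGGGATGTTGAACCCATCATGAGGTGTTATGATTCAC) the mean signal was 83.2 ± 41.2 (SD, n = 5) at Chioggia and 3.41 ± 1.69 (SD, n = 5) at Marghera. In the processed signals its level was at least 7.91-fold lower at Marghera, a bound taken against the lowest signal of probes well above background on each array (limma, adjusted p = 9.8e-05). Probe ruditapesP2_lrc5035_1 (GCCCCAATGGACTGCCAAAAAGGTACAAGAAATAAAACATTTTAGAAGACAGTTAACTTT) gave a signal of 60.9 ± 36.7 (SD, n = 5) at Chioggia and 12.5 ± 14.8 (SD, n = 5) at Marghera, where 2 of the 5 arrays were well above background. With 3 arrays not well above background no size is given for this lower level (limma, adjusted p = 0.030), and the call was lost under 12 of 31 alternatives, among them leaving out Chioggia replicate 2 or 4 or Marghera replicate 1, 3 or 4. In all 4 probes the 5 Marghera arrays lay on one side of the 5 Chioggia arrays, as the naming rule required. Under normexp the log2 differences of ruditapesP_c10932_1 and ruditapes_c21049_S were 0.54 and 0.25 and both calls were lost; with outlying backgrounds replaced they were 1.71 and 1.32 and both calls held. The fitted log2 difference of ruditapes2_lrc4903_AS was -1.89 under normexp and -1.18 with outlying backgrounds replaced, and the call held in both. The normexp offset shrinks log2 differences of such dim probes, so these sizes are not set against the bound above or the main values. Within slide 1, with 2 Marghera and 3 Chioggia arrays, the calls of ruditapes_c21049_S and ruditapes2_lrc4903_AS were lost, while the log2 difference of ruditapes_c21049_S was 3.00 there and ruditapes2_lrc4903_AS kept its direction.

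The 5 Marghera arrays did not overlap the 5 Chioggia arrays for 720 probes, 7.83% of those tested, where 0.794% would do so by chance. With slide as a block 443 probes passed the threshold, and within the slides taken alone 34 passed on slide 1 and 58 on slide 2. The number was 113 under normexp and 398 with outlying backgrounds replaced. It was 307 with no filter, 790 with array weights, 305 without Marghera replicate 2 and 307 without Chioggia replicate 5.

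Set against Colmata, the other site of low pollution, Marghera differed at 290 probes, 137 higher and 153 lower, with a median size of 0.96 log2. At least a 2-fold change was seen for 134 of them, 75 higher and 59 lower. The naming rule took ruditapesP_c10932_1 and ruditapesP_c4594 as higher, and ruditapesP2_lrc3224 and ruditapesP2_c435 as lower. Probe ruditapesP2_c435, well above background on all arrays of both sites, was 4.64-fold lower at Marghera.

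The level of ruditapesP_c10932_1 was 3.19 log2 higher at Marghera than at Colmata (SE 0.46; limma, adjusted p = 0.0017), where its signal was 17.3 ± 4.42 (SD, n = 5). Probe ruditapesP_c4594 (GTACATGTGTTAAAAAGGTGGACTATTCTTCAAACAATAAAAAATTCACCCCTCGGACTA) had a signal of 187 ± 112 (SD, n = 5) at Marghera and 31.1 ± 42.9 (SD, n = 5) at Colmata, a log2 difference of 3.17 (SE 0.71; limma, adjusted p = 0.027). On Colmata replicate 5 this probe was not well above background. Its call was lost under 11 of 31 alternatives, among them leaving out Colmata replicate 1, 2 or 4 or Marghera replicate 4 or 5. The signal of ruditapesP2_c435 (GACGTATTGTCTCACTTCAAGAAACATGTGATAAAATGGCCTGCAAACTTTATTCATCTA) was 87.1 ± 47.9 (SD, n = 5) at Marghera and 374 ± 134 (SD, n = 5) at Colmata, a log2 difference of -2.21 (SE 0.39; limma, adjusted p = 0.0063). Probe ruditapesP2_lrc3224 (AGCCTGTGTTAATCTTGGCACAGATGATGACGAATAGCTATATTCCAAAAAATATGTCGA) was not well above background on any Marghera array and was lower there than at Colmata, where 3 of the 5 arrays measured it (limma, adjusted p = 5.8e-04). The bound of 1.34-fold is not firm, because Colmata replicates 1 and 2 were not well above background and entered at their own signals. This probe shares a stretch of 30 bases with 3 other probes, so its signal is not separated from theirs. One of these that was tested, ruditapesP2_lrc3498, was also not well above background on any Marghera array, and on 2 of the 5 at Colmata, so no size is given for its lower level at Marghera (limma, adjusted p = 0.0031). In each of the 4 named probes the 5 Marghera arrays lay on one side of the 5 Colmata arrays, as the naming rule required. All 4 calls were lost under normexp, where the log2 differences of ruditapesP_c10932_1, ruditapesP_c4594 and ruditapesP2_c435 were 1.68, 1.44 and -1.49 and that of ruditapesP2_lrc3224 -0.06. With outlying backgrounds replaced the calls of these 3 held, with log2 differences of 1.64, 1.35 and -1.58, and that of ruditapesP2_lrc3224 was lost at -0.28. The normexp offset shrinks such differences, so they are not set against the bound or the main values. Within slide 1, with 2 arrays of each site, all 4 calls were lost, while the log2 differences of the 3 were 3.03, 3.57 and -2.06 and ruditapesP2_lrc3224 kept its direction. Within slide 2 the calls of ruditapesP_c4594 and ruditapesP2_c435 were lost, with log2 differences of 2.90 and -2.32.

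The 5 Marghera arrays did not overlap the 5 Colmata arrays for 448 probes, 4.87% of those tested, where 0.794% would do so by chance. With slide as a block 316 probes passed, within slide 2 alone 25, and within slide 1 alone 0 by limma, where 1036 had an unadjusted p under 0.05. The number was 19 under normexp (84.2% of them higher at Marghera) and 323 with outlying backgrounds replaced. It was 149 with no filter, 147 with only these sites in the fit, 148 without Marghera replicate 3 and 156 without Colmata replicate 4. It was 179 without Marghera replicate 2, 179 without Marghera replicate 5 and 185 without Colmata replicate 1. Whether more of the probes were higher or lower at Marghera depended on the settings: 47.2% of the 290 were higher, against 54.0% with quantile scaling, 55.4% with cyclic loess, 51.9% with median scaling, 55.7% in the series value table, 59.9% with only these sites in the fit and 40.4% without Colmata replicate 5.

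Probes that set Marghera apart from both other sites were counted next. In both Marghera comparisons 150 probes changed in the same direction, 101 higher and 49 lower at Marghera, and 0 changed in opposite directions. Probe ruditapes_c23230_S, well above background on all arrays, was 8.45-fold higher at Marghera than at Chioggia and 8.29-fold higher than at Colmata. The named probes ruditapesP_c10932_1, ruditapes_c21049_S and ruditapesP_c4594 were also higher in both comparisons, and ruditapesP2_lrc5035_1, ruditapesP2_lrc3224 and ruditapesP2_c435 lower in both.

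The signal of ruditapes_c23230_S (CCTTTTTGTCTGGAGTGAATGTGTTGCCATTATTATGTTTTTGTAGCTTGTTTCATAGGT) was 834 ± 282 (SD, n = 5) at Marghera, 93.4 ± 28.0 (SD, n = 5) at Chioggia and 96.7 ± 36.5 (SD, n = 5) at Colmata. It was higher at Marghera by 3.08 log2 than at Chioggia (SE 0.22; limma, adjusted p = 4.1e-06) and by 3.05 log2 than at Colmata (SE 0.22; limma, adjusted p = 5.7e-06). Between Colmata and Chioggia it differed by 0.03 log2 (SE 0.22; limma, adjusted p = 0.98). Probe ruditapesP2_lrc5035_1 was also lower at Marghera than at Colmata (limma, adjusted p = 0.036), with no size given because 3 Marghera arrays were not well above background. The arrays overlapped, Marghera replicate 2 lying above Colmata replicate 1, and the call was lost under 16 of 31 alternatives, among them leaving out Colmata replicate 2, 3, 4 or 5 or Marghera replicate 1, 3 or 4. Probe ruditapesP2_lrc3224 was also lower at Marghera than at Chioggia (limma, adjusted p = 8.6e-05). The bound of 1.80-fold is not firm, because Chioggia replicate 2 was not well above background and entered at its own signal. The calls of this probe in both comparisons were lost under normexp, with outlying backgrounds replaced or not (fitted log2 differences against Chioggia of -0.44 and -1.41). They were also lost within slide 1, where its direction was kept. The change of ruditapes_c23230_S against Chioggia was 1.51 log2 under normexp, where the call was lost, and 2.38 log2 with outlying backgrounds replaced, and both its calls were lost within slide 1, where the log2 differences were 2.60 against Chioggia and 2.90 against Colmata.

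Both comparisons use the same Marghera arrays, so their values are related with no effect at all. Unchanged groups simulated 100 times shared 0 probes each time, but they hold no site effect to call. That 0 therefore does not set the overlap to expect from lists of the real lengths. Independent lists of these lengths would share 7.25, a value that leaves out the shared arrays. Over probes, which are not independent replicates, the log2 changes had a correlation of 0.66 and a covariance of 0.180, where the simulated groups gave 0.50 and 0.0606, a difference in covariance of 0.119. With the Marghera arrays split into 2 and 3, so that each comparison had its own, the 20 splits shared a median of 41 probes (range 26 to 50) with a median correlation of 0.298. The number of shared probes was 154 with slide as a block, 20 within slide 2 and 0 within slide 1. It was 12 under normexp and 153 with outlying backgrounds replaced. It was 89 with no filter, 92 with only the sites compared and 232 with array weights. It fell to 87 without Marghera replicate 3, 93 without Marghera replicate 2 and 93 without Colmata replicate 4.

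**Figure D2:**
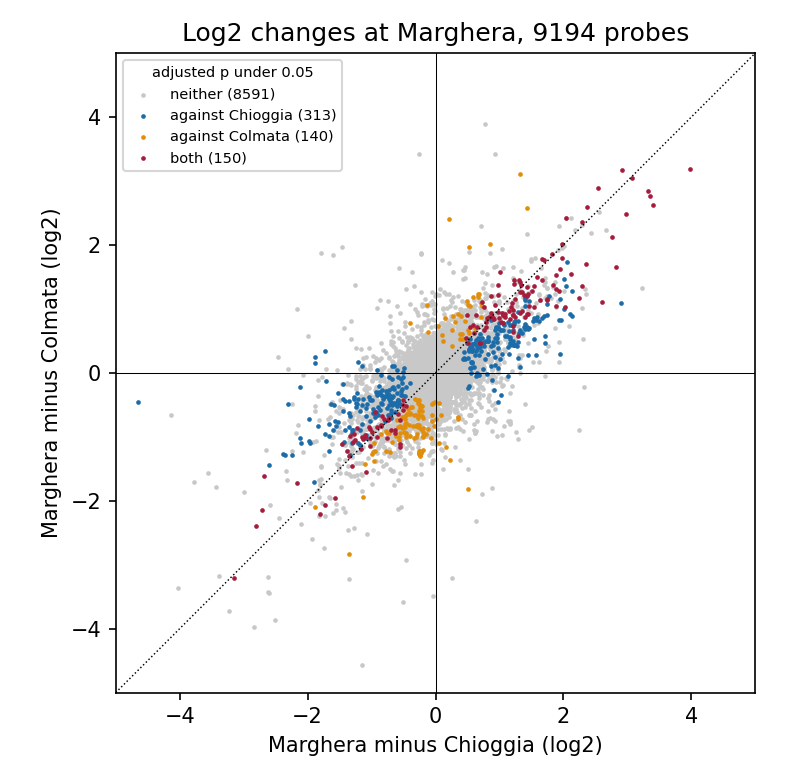
Log2 change of each of the 9194 tested probes at Marghera against Chioggia (horizontal axis) and against Colmata (vertical axis), coloured by the comparisons in which limma's adjusted p was under 0.05; the dotted line marks equal changes. The 150 probes called in both lie in the upper right and the lower left, and the shared Marghera arrays alone give a correlation of 0.50.

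The planned contrast of Marghera with the mean of the other sites gave 498 probes, 261 higher and 237 lower at Marghera, of which 182 changed by at least 2-fold. The median size of the changes was 0.84 log2. With slide as a block 502 probes passed, and within slides 1 and 2 taken alone 10 and 86 passed. Under normexp 78 passed, and with outlying backgrounds replaced 465. Of the 78, 75.6% were higher at Marghera, against 52.4% of the 498, while array weights gave 48.7%. Leaving out Marghera replicate 3 gave 324 probes, and leaving out Marghera replicate 2 gave 329.

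The sites of low pollution were compared as the background for the Marghera comparisons. Colmata and Chioggia differed at 95 probes, 55 higher and 40 lower at Colmata, with a median size of 0.98 log2, and 44 of them changed by at least 2-fold. The probes named as higher at Colmata were ruditapes2_c57_S and ruditapes_lrc27075_AS, both not well above background on any Chioggia array. Those named as lower were ruditapes2_lrc4903_AS and ruditapesP_c2092_1.

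Probe ruditapesP_c2092_1 (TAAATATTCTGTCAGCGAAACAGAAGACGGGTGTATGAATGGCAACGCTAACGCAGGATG) gave a signal of 684 ± 258 (SD, n = 5) at Chioggia, 153 ± 62.5 (SD, n = 5) at Colmata and 180 ± 39.3 (SD, n = 5) at Marghera. Its log2 difference was -2.14 at Colmata against Chioggia (SE 0.31; limma, adjusted p = 0.0080) and -1.89 at Marghera against Chioggia (SE 0.31; limma, adjusted p = 0.0019). The signal of ruditapes2_lrc4903_AS at Colmata was 5.13 ± 4.47 (SD, n = 5), well above background on only 1 of the 5 arrays, so no size is given for its lower level there than at Chioggia (limma, adjusted p = 0.0022), a call lost under normexp. Both lost their calls within slide 1 and within slide 2, with 2 or 3 arrays of each site, while the log2 difference of ruditapesP_c2092_1 was -1.94 and -2.01 there and ruditapes2_lrc4903_AS kept its direction. Probe ruditapes_lrc27075_AS (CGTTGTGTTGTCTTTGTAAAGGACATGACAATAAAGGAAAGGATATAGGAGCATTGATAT) was measured on all Colmata arrays, with a signal of 21.9 ± 6.86 (SD, n = 5), and was at least 2.43-fold higher there than at Chioggia (limma, adjusted p = 0.027). Probe ruditapes2_c57_S (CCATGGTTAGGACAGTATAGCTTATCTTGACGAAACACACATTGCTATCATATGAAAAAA) was measured on 4 of the 5 Colmata arrays and was higher there than at Chioggia (limma, adjusted p = 0.043). The bound of 2.18-fold is not firm, because Colmata replicate 1 was not well above background and entered at its own signal. The calls of ruditapes2_c57_S and ruditapes_lrc27075_AS were lost under 18 and 12 of the 30 alternative settings, and in each the log2 difference changed sign under normexp (-0.88 and -0.95), without the calls. With outlying backgrounds replaced the log2 differences were 0.42 and 0.30, the sign seen without normexp, but again without the calls. The call of ruditapes2_c57_S was lost when any array of Chioggia or Colmata, or Marghera replicate 4, was left out, and that of ruditapes_lrc27075_AS without Chioggia replicate 1, 2 or 5 or Colmata replicate 1, 2 or 4.

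Chioggia and Colmata each also had probes apart from both other sites. For Chioggia there were 31, 17 higher and 14 lower there, and they include ruditapesP_c2092_1 and ruditapes2_lrc4903_AS. For Colmata there were 25, 22 higher and 3 lower, and they include ruditapes_lrc27075_AS. Independent lists would give 2.44 and 1.51 such probes, values that leave out the arrays shared by the comparisons. In 100 simulations of unchanged groups 0 were seen each time, but such groups hold no site effect to call. The shared arrays were not split here, so how many probes they alone would give was not tested. The difference between the 31, the 25 and the 150 of Marghera was not tested.

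The number of probes that separated Colmata from Chioggia depended on the settings and on single arrays. It was 8 under normexp and 123 with outlying backgrounds replaced. It was 23 with only these sites in the fit, 40 with no filter, 152 with a variance trend and robust estimation and 188 with array weights. Without Colmata replicate 3 and Marghera replicate 1 together it was 167. It was 22 without Colmata replicate 2 (45.5% of them higher at Colmata, against 57.9% of the 95), 28 without Chioggia replicate 2, 42 and 44 without Colmata replicates 4 and 1, and 51, 57 and 61 without Chioggia replicates 4, 5 and 1. With slide as a block 114 probes passed, while within slides 1 and 2 taken alone 1 and 0 passed by limma, with 1045 and 897 at an unadjusted p under 0.05.

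**Figure D3:**
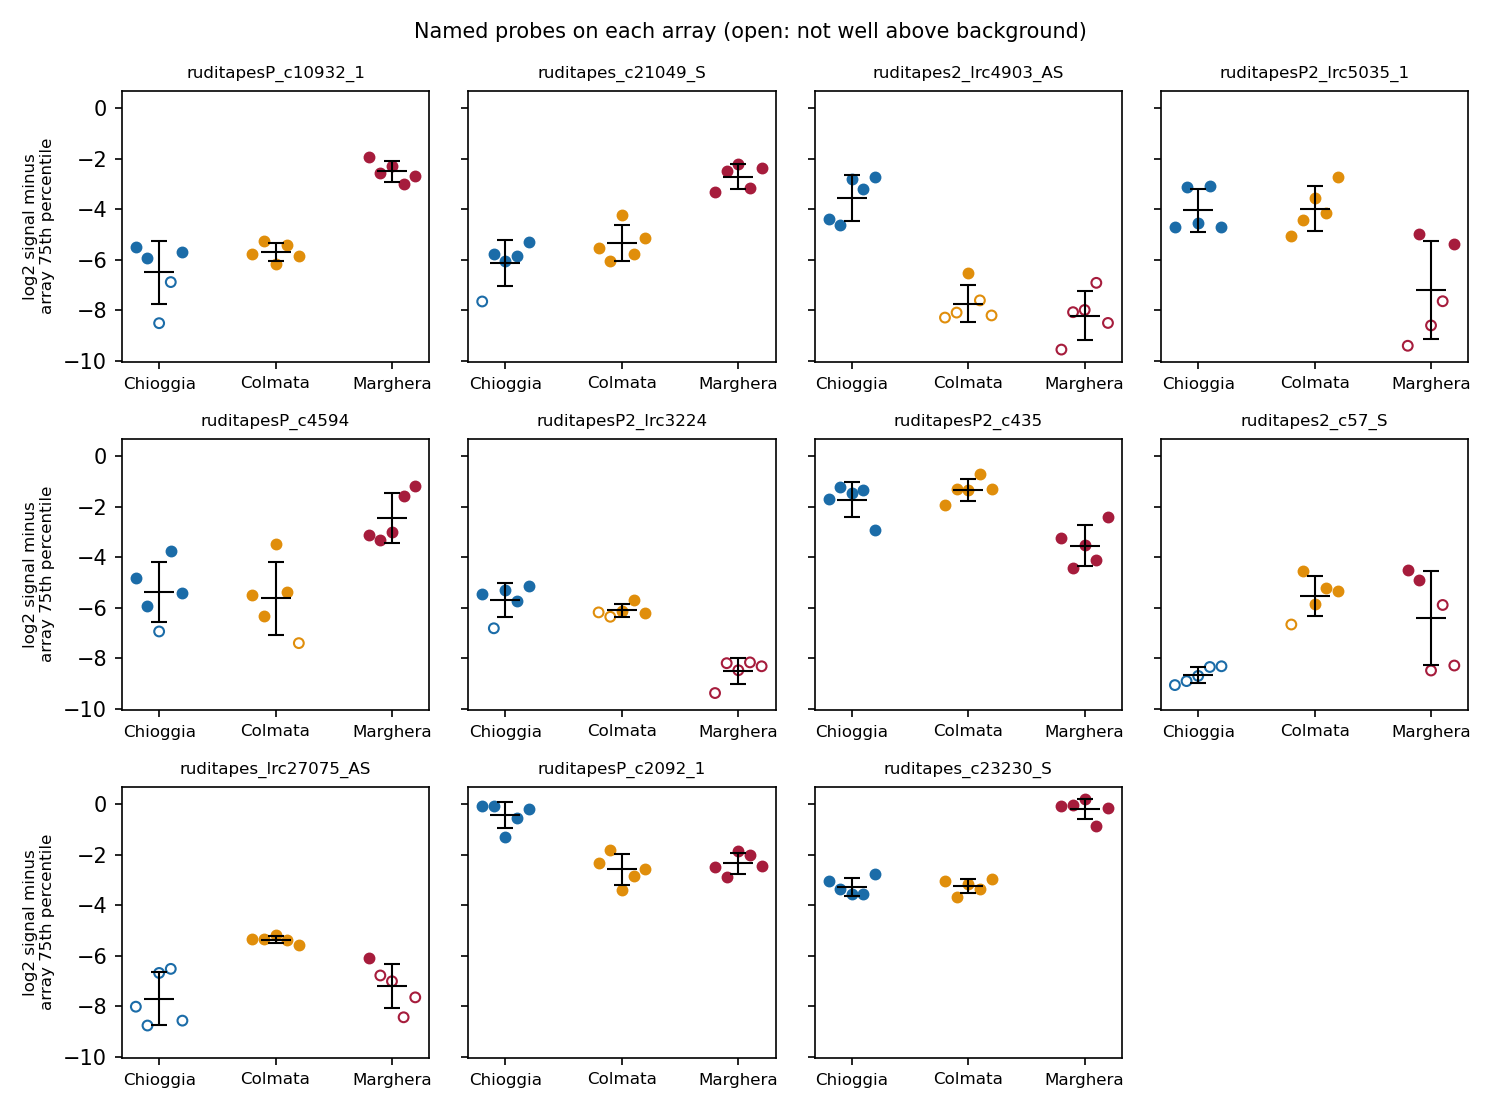
Normalized log2 signal (log2 signal minus the 75th percentile of its array) of the 11 named probes on each array, by site; open points are not well above background, and the black bars are the mean and SD of 5 arrays. Probe ruditapes_c23230_S is higher on all 5 Marghera arrays (-0.86 to 0.19) than on any array of Chioggia or Colmata (-3.69 to -2.77).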

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

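The tests of how many of the 150 probes remain with slide or row as a block, the slide itself being a block that was planned, were chosen only after the counts had been seen. Among 57 groups of 5 values, made of array measures and the named probes at each site, 4 held a value far from the others of its site, where chance gives about 1 in 20, or 2.85. The spread of the negative control spots was 18.2 on Chioggia replicate 3, where the other arrays of the site had 1.64 to 3.84. It was 15.03 on Colmata replicate 3 against 2.55 to 5.30 on the other arrays of that site. Both arrays lay in columns 1 and 2 of slide 2, as did Marghera replicates 2 and 3. The Marghera arrays of slide 2 had 8.92 to 12.3, and those of slide 1 had 1.39 and 2.79. In columns 3 and 4 of slide 2 the spread was 2.55 to 8.92, and on slide 1 it was 1.39 to 5.30. The high values were thus shared by arrays in 1 part of slide 2, and their cause was not tested. A search for single far values cannot flag them at Marghera. The median local background was 39 on Chioggia replicate 4 and 42 to 43 on the other Chioggia arrays. The normalized level of ruditapesP2_lrc3224 was -9.37 log2 on Marghera replicate 1 and -8.47 to -8.15 on the other Marghera arrays, all of them not well above background.

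Chance placement of the arrays was excluded as the source of the counts at the 5% level. Of 100 splits of the 10 arrays of each pair of sites, the real one included, 1 gave as many probes as the real split for Marghera against Chioggia (463 probes, highest other 9), 1 for Marghera against Colmata (290, highest other 1) and 1 for Colmata against Chioggia (95, highest other 1). Of 100 relabelings of all 15 arrays, 1 gave as many for Marghera against the mean of the others (498, highest other 6) and 1 for the probes shared by both Marghera comparisons (150, highest other 1). The split of the Chioggia and Marghera arrays that follows the slides gave 3 probes. Each group of that split holds arrays of both sites, whose differences widen the spread, so the 3 does not measure the slide effect.

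The pattern weighed here is the set of 150 probes that set Marghera apart from both other sites. A difference between the slides, the row of the array on the slide and the brightness of the array were each tested as the whole cause. The column on the slide was not tested. With slide as a block 136 of the 150 were still called in both comparisons, with the row on the slide 98, and with the 75th percentile of the array as a covariate 132, so none of these is the cause of the whole set. Colmata and Marghera had the same numbers of arrays on each slide. The slide term could therefore move the size of a change mainly against Chioggia. At Marghera only replicate 1 lay in row 1, against Chioggia replicates 1 to 3 and Colmata replicates 3 to 5, so row and site were partly mixed. The mean 75th percentile was 872 at Chioggia, 896 at Colmata and 906 at Marghera, so that covariate could move the sizes only little. The 52 probes that lost a call with the row kept their direction, and in each comparison 35 of the changes were smaller, with a median size of 0.83 log2 against Chioggia (0.88 before) and 0.85 against Colmata (0.85 before), and the median SE was 0.20 (0.18 before). The biological explanation that the design names, a difference between the sites, stays open as a hypothesis, and with 1 polluted site its pollution was not tested apart from anything else that differs there.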

How the results depend on the processing

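Fits within slides, with the row on the slide, without 2 arrays together, and with replaced backgrounds were chosen after seeing the data; other settings were planned. Quantile, cyclic loess and median scaling, the series value table, the stricter filter, and slide or row as a block kept all 5 counts within 1.5 times, but the share of Marghera against Colmata calls higher at Marghera (47.2%) was 51.9% to 55.7% with these 3 scalings and the series value table. Of 498 values of named probes under alternatives, 404 kept direction and call, 92 lost the call and 2 changed sign, ruditapes2_c57_S (-0.88) and ruditapes_lrc27075_AS (-0.95), both for Colmata against Chioggia under normexp; with outlying backgrounds replaced both kept the sign seen without normexp (0.42 and 0.30), without the call. Counts below are in the order Marghera against Chioggia, Marghera against Colmata, Colmata against Chioggia, Marghera against the mean of the others, and shared by both Marghera comparisons (463, 290, 95, 498 and 150).

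Normexp gave 113, 19, 8, 78 and 12, with 84.2% of the Marghera against Colmata calls higher (47.2% before) and 75.6% of those against the mean (52.4% before), and the median of all probes for Marghera against Chioggia was -0.32 log2 (-0.04 before). On Chioggia replicates 2 and 4 1 spot minus its local background came to -47717 and -50931, and the fitted mean was -1291 and -1043 there, -92.7 on Marghera replicate 1 and -13.6 to -6.60 on the others. With backgrounds over 2 times the median of the array replaced by that median, normexp gave 398, 323, 123, 465 and 153.

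With no filter the counts were 307, 149 and 40, and 89 were shared. Fits of only the sites compared gave 147 for Marghera against Colmata, 23 for Colmata against Chioggia and 92 shared. Array weights gave 790, 188 for Colmata against Chioggia and 232 shared. A variance trend with robust estimation gave 152 for Colmata against Chioggia, and the fit without Colmata replicate 3 and Marghera replicate 1 together 167. For these settings the cause was not tested. A 2-fold minimum left 246, 134, 44, 182 and 74. With fewer arrays, slide 1 alone gave 34, 0, 1, 10 and 0, and slide 2 alone 58, 25, 0, 86 and 20 (unadjusted p under 0.05 by limma for 1036 probes where slide 1 gave 0 and 897 where slide 2 did).

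Leaving out 1 array gave 305 (Marghera 2) to 573 (Colmata 3), 148 (Marghera 3) to 317 (Colmata 5), 22 (Colmata 2) to 129 (Colmata 3), 324 (Marghera 3) to 546 (Colmata 3) and 87 (Marghera 3) to 147 (Colmata 3). With the replicate number as a block the counts were 404, 224, 38, 471 and 119. The numbers do not pair the arrays: 1 of 15 same-number pairs had a correlation of deviations over 0.1 (median 0.013), and 2 of 15 arrays correlated best with their own number. The settings for gene lists were not run, since the lists matched 0 probes. Signal over background limits ruditapes2_lrc4903_AS and ruditapesP2_lrc3224 at Marghera, and ruditapes2_c57_S and ruditapes_lrc27075_AS at Chioggia, to bounds. Those of ruditapesP2_lrc3224 and ruditapes2_c57_S are not firm, because arrays of the brighter site were also not well above background.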

Other observations

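Tests of chance pairing and of place on the slide in this part were chosen only after the results had been seen. Some contigs were represented by probes named as opposite orientations. Kinds of probe pairs were taken as opposite because their overlapping members lay mainly on opposite strands. The opposite orientation was thus read from the sequences for 210 of the 2230 contigs of these kinds. The 3 that overlapped on the same strand were left out, and for the rest the orientation was inferred from the names. Both probes were tested for 576 pairs. Of the 54 pairs in which at least 1 probe differed between Marghera and Chioggia, 51 changed in the same direction, and in all 15 pairs with both probes called the direction was shared. Over the pairs, which are not independent replicates, the log2 changes had a correlation of 0.57, against at most 0.105 in 1000 shuffles of the partners, which argues against chance pairing of probes. Over the 64 tested pairs that overlap on opposite strands it was 0.64, against at most 0.405 in the shuffles. A candidate explanation is a labelled by-product of 1 strand at a fixed yield, which predicts equal log2 changes. The partner of a called probe changed by a median of 0.794 of the called probe's change (95% bootstrap interval 0.643 to 0.913), which lies between the values set for and against it, so a by-product and transcription of both strands cannot be told apart. The interval treats 69 ratios from the 54 pairs as independent, although the 15 pairs with both probes called entered in both directions. The called probe was chosen for its change, which tends to lower the ratio.

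Colmata replicate 3 and Marghera replicate 1, the arrays at one end of the next principal component, shared 24 probes that were at least 4-fold above the other arrays of their own site, where independent lists would share 1.35. This was the highest number among 75 pairs of arrays from different sites. Colmata replicate 3 and Marghera replicate 1 also had the longest lists of such raised probes, 114 and 109. Chioggia replicate 1 and Marghera replicate 2 shared 20, where independent lists would share 0.481. Each of the 75 pairs shared more than independent lists would. Of the 24 probes, 0 were called by limma in any of the 3 comparisons between sites. They were chosen for a large spread within Colmata and Marghera, which makes such calls unlikely, so this 0 does not show whether they differ between sites. Noise near background stays open: the 24 were well above background on 73.1% of the other 13 arrays, as a median over probes, between the values set for and against it. The place of the array on the slide stays open: over these probes the other row 1 arrays lay 1.04 log2 above the row 2 arrays at Colmata, where row and slide coincide, and 0.40 at Chioggia. Material of another tissue in the dissected gland may also raise such probes and cannot be told apart, because the tissue lists matched 0 probes; no biological explanation was tested.

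The median SD of tested probes between arrays was 0.36 log2 at Colmata, 0.30 at Chioggia and 0.30 at Marghera. Without Colmata replicate 3 the value at Colmata was 0.28, and without Marghera replicate 1 that at Marghera was 0.27. Colmata replicate 3 also had the lowest array weight in limma, 0.289, where the other arrays had 0.665 to 1.59.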
